A study of Mus musculus with 10 samples.

How the data were processed

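RNA was sequenced from 10 libraries of sorted 4T1 tumour macrophages, 5 PDPN-positive and 5 PDPN-negative, each pair from a tumour of the same number (1, 2, 4, 5 and 6). Per the labels' protocols, tumours were digested enzymatically, red blood cells were lysed, viable cells positive for CD11B and F4/80 were sorted with or without PDPN, and RNA was pre-amplified with SMART-Seq. Such amplification carries no molecular identifiers here, so counts are reads, not molecules, and any floor covers counting error only. The authors deposited a single table of raw counts per gene, with Ensembl gene identifiers and gene names for 46603 genes. Per the submitters' processing notes, cutadapt 1.15, Bowtie2 2.3.3.1, STAR 2.5.2b and featureCounts 1.5.3 were used; the role and settings of each tool, the genome build, the annotation and the treatment of multi-mapping reads and strand are not given in the sources used here. The counts were whole numbers with a different total in each library, and 0 counts lay in rows without a gene. Counts of genes with near-identical copies or pseudogenes, of overlapping genes and of antisense genes are therefore uncertain.

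Groups were taken from the labels. Columns were matched to samples by their titles. Library totals ran from 12597829 to 15406722 counts, and between 18509 and 19293 genes had at least 1 count in a library. The share of counts in the 10 most abundant genes was 6.84% ± 0.278 in PDPN-negative and 7.38% ± 0.277 in PDPN-positive libraries (SD, n = 5 each, exact permutation test, two-sided p = 0.0238, and 0.0952 after adjustment over 4 library measures). That share was higher in the PDPN-positive library of 5 of 5 tumours (exact paired p = 0.0625, the smallest that 5 pairs allow, and 0.25 after adjustment over the 4 measures). The share of mitochondrially encoded counts was alike (0.595% ± 0.140 and 0.585% ± 0.0790, exact permutation p = 0.905). No libraries of a group agreed within sampling noise: the chi-square per gene between libraries of the same group was at least 7.58. Gene positions came from GENCODE M21 (GRCm38), to which 46091 identifiers matched; this build was not stated for the counts, and positions are given for identification only.

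Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 13595; 22630 genes had no count in any library. Libraries were scaled with TMM, and a quasi-likelihood model with group as its only term was fitted with robust dispersions (glmQLFit, glmQLFTest). The common biological coefficient of variation was 13.3%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are fitted values, and CPM are TMM-scaled counts relative to the library total with the SD over 5 libraries. The SE of a log2 fold change was derived from the test, as its absolute value divided by the square root of the quasi-likelihood F statistic. It therefore adds no information to the p-value. Fixed lists (19 gene lists and 16 cell type marker lists) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, two-sided, with adjustment over the 33 lists with at least 3 tested members. Camera with an estimated correlation was run beside it, as was fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. A list whose members move both ways can miss these tests. Fry was therefore also run for changes in either direction, and is named so where used. It called the lists that camera at the preset correlation did not, with these exceptions. Nuclear oxidative phosphorylation had adjusted p = 0.212, mitochondrially encoded genes 0.681, plasmacytoid dendritic cell markers 0.319 and lymphatic endothelial markers 0.732. Of the 17 lists called with the preset correlation, 8 were also called with an estimated one: structural matrix proteins, matrix remodelling, hypoxia and glycolysis, dissociation stress and immediate early genes, and the markers of neutrophils, mast cells and basophils, eosinophils and fibroblasts. When the tumour was also a block, hypoxia and glycolysis, dissociation stress and immediate early genes and mast cells and basophils were no longer called.

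The lists, the tests and the genes to be named were chosen before the data were examined. Named were the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold with a mean log2 CPM of at least 3 and the same sign in all 5 tumours (predicted genes and pseudogenes apart), up to 4 members of each list by lowest p (2 where none passed), and Pdpn, Itgam, Adgre1, Csf1r, Cd68, Ptprc, Lgals8, Itgb1, Vegfc, Flt4, Lyve1, Col1a1 and Epcam. Genes named outside this rule are Lama5, Hsph1, Hspa1b, Hspa1a, Hsp90aa1, Gapdh and Prg2 and, in the closing section, the further genes named there; they were chosen after their values were seen. Genes below the filter were compared by exact permutation of the CPM (252 assignments, or 32 sign assignments for pairs), two-sided.

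The tumour numbers pair the samples, because both libraries of a number come from the same tumour. Deviations from the group means correlated within tumours (r across genes of 0.50, 0.45, 0.24, 0.45 and 0.44 for tumours 1, 2, 4, 5 and 6). Genes are not independent replicates. Between a PDPN-negative and a PDPN-positive library of different tumours, r was at most 0.087. Centring on the group means lowers these values where those within tumours are positive, so they were partly fixed in advance. The block lowered the common biological coefficient of variation to 7.55%. The fit without the block was kept as planned, and blocked values are given where they change the call of a named gene or list. Counts of list members are without the block unless stated, and were larger with it in many lists. With the block, structural matrix had 38 higher and 2 lower, and matrix remodelling 34 and 6. Hypoxia and glycolysis had 34 higher and 2 lower, proliferation 36 and 0, and MHC class II 0 and 10.

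Alternatives were the tumour as a block, DESeq2 1.42.0 size factors, upper quartile scaling or library size alone in place of TMM, no filter on low counts and a stricter one (5 CPM in at least 5 libraries), the DESeq2 Wald test with and without the block, limma-voom with quality weights or with the tumour as a random effect, glmTreat against a 1.5-fold change, and leaving out each library or tumour. The list tests were run with the block, the other scalings, the stricter filter and each library left out, and not with DESeq2, limma-voom, glmTreat, no filter or a tumour left out. Chosen after seeing the data were a GC correction in the blocked fit (loess of log2 counts on transcript GC content, span 0.3, which covered 99.7% of tested genes) and the structural matrix list without fibroblast markers. The scripts were tested on counts simulated for this comparison from the real means and library sizes with 200 changed genes. On 13488 simulated genes, the test recovered 80.6% of changes of 1.5-fold, 88.1% of 2-fold and 98.5% of 4-fold, and 3.78% of its calls were false. DESeq2 made 12.2% false calls in the same simulation, and the blocked fit 5.88%. The simulated counts held no tumour effect and fewer changed genes than were called in the data. These rates therefore need not hold for the paired libraries measured here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.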

Results

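Macrophages of 4T1 tumours were profiled by RNA sequencing after sorting on podoplanin (PDPN), a membrane glycoprotein best known from lymphatic endothelium and activated fibroblasts. 4T1 is a mouse mammary carcinoma cell line that forms tumours when grafted into mice. Viable cells positive for CD11B and F4/80, the usual surface pair for mouse macrophages, were split into a PDPN-positive fraction, called PoEMs by the submitters, and a PDPN-negative fraction. Both fractions were taken from each of 5 tumours, numbered 1, 2, 4, 5 and 6, which gave 10 libraries in 2 groups of 5. The values were raw read counts for 46603 genes. Between 12597829 and 15406722 counts were assigned to genes per library, so that 1 count corresponded to 0.0649 to 0.0794 CPM, the read count scaled to the library total. Total counts averaged 13979400 ± 1024800 (SD, n = 5) in the PDPN-negative and 13834200 ± 635073 (SD, n = 5) in the PDPN-positive libraries, a difference within the spread between libraries (exact permutation test, two-sided p = 0.802, and 0.905 after Benjamini-Hochberg adjustment over 4 library measures). The labels number the tumours but do not say whether each came from a separate mouse, so p-values speak for these tumours and not for mice. Those without the tumour as a block measure the spread between libraries within each sorted fraction. Those with the block measure the spread of the difference within tumours.

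The stated purpose of the study was the part played by PDPN-positive tumour macrophages in the growth of lymphatic vessels and in the remodelling of the extracellular matrix. The central comparison therefore asked which genes differed between the PDPN-positive and the PDPN-negative fraction. Pdpn itself (ENSMUSG00000028583, chromosome 4, 143267431 to 143299564 of GRCm38, minus strand, protein-coding) separated the groups: it measured 214.5 ± 22.9 CPM (SD, n = 5) in the PDPN-positive and 19.3 ± 7.33 CPM (SD, n = 5) in the PDPN-negative libraries, a log2 fold change of 3.48 ± 0.24 (SE, edgeR quasi-likelihood test, adjusted p = 1.96e-05), and was higher in 5 of 5 tumours. The mRNA of the sort markers shared by both fractions moved little. Itgam, which encodes CD11B, was 1.17-fold higher (edgeR adjusted p = 0.0347, and 0.0875 at most with a library left out). By contrast, Adgre1, which encodes F4/80, differed by -0.12 ± 0.10 on the log2 scale (SE, adjusted p = 0.463).

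Many of the largest gains in PDPN-positive libraries were in genes of the fibrillar matrix, and the largest losses included markers of eosinophils, neutrophils and monocytes. Among the 13595 genes tested, 929 were higher and 920 lower in PDPN-positive libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 207 and 167 of the fitted changes, respectively, were at least 2-fold. Apart from Pdpn, the genes with the largest increase among those with a mean log2 CPM of at least 3 and the same sign in all 5 tumours were the collagen genes Col12a1, Col3a1, Col1a2, Col1a1, Col5a2 and Col6a3, the matrix glycoprotein genes Tnc (tenascin C) and Postn (periostin), and Adm, which encodes the vasoactive peptide adrenomedullin. Under the same limits, the genes with the largest decrease were Retnlg, Ccr3, G0s2, Sema7a, Alox15, Serpinb2, Siglecf, Ctsk, Ly6c2 and Adora2a. With the tumour as a block, the counts were 1880 higher and 1950 lower, and 1846 of the 1849 genes called without the block were called again, all in the same direction. In the fit without the block, leaving out 1 library moved a count by over 1.5 times for PDPN-negative tumour 2 (577 lower) and PDPN-positive tumour 4 (617 higher, 588 lower), as did leaving out both libraries of tumour 2 (514 higher, 503 lower), tumour 4 (437 higher, 482 lower) or tumour 5 (595 higher, 494 lower). With the block kept, leaving out both libraries of any tumour moved neither count by over 1.5 times.

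**Figure D1:**
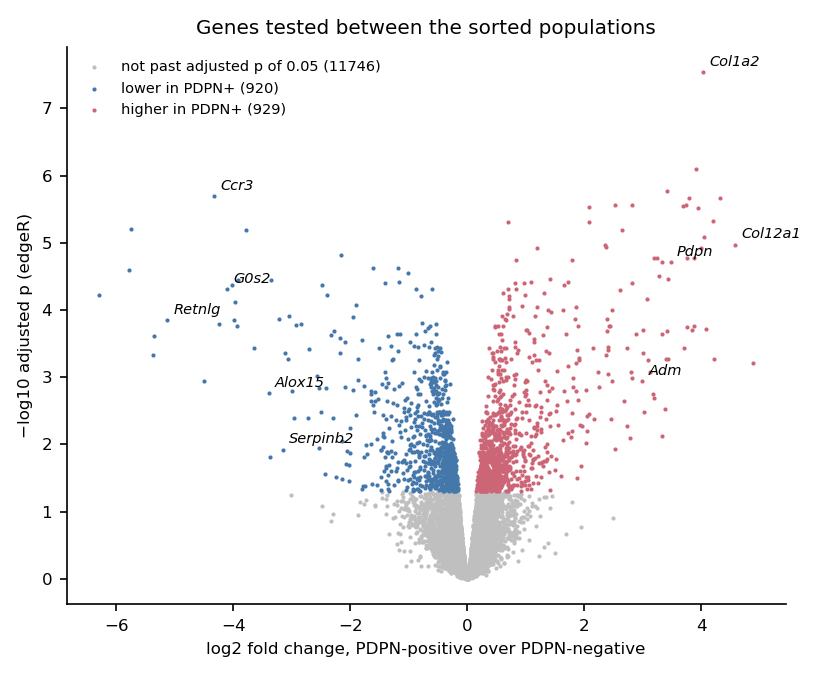
Each point is a gene of the 13595 tested, with its log2 fold change (PDPN-positive over PDPN-negative, n = 5 each) on the horizontal axis and the negative log10 of the edgeR adjusted p on the vertical axis. Red points are the 929 genes higher and blue points the 920 genes lower in PDPN-positive libraries, with Col1a2 at the top right and Ccr3 among the strongest decreases.

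Structural matrix genes rose together in PDPN-positive libraries. Of 48 tested members of the list of structural matrix proteins, 29 were higher and 1, the laminin gene Lama5, was lower, and adjusted over the list alone 33 were higher and 2 lower. The list median was 1.24 on the log2 scale (camera adjusted p = 3.39e-65, and adjusted p = 0.00255 with an estimated correlation). Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544) measured 79.7 ± 13.03 CPM against 4.85 ± 0.826 CPM in the PDPN-negative libraries (SD, n = 5 each), a log2 fold change of 4.03 ± 0.15 (SE, edgeR adjusted p = 2.9e-08). Its partner in type I collagen, Col1a1, measured 121.9 ± 23.0 against 7.91 ± 2.296 CPM. The largest change in the list was in Col12a1, at 22.7 ± 5.05 against 0.955 ± 0.554 CPM, a log2 fold change of 4.59 ± 0.32 (SE, edgeR adjusted p = 1.07e-05). Bgn, which encodes the small proteoglycan biglycan, rose by 2.53 ± 0.17 on the log2 scale. Of these matrix genes, 10 are also fibroblast markers, and the fibroblast marker list rose in the same libraries, with 16 of 19 members higher (median 2.81 on the log2 scale). Without those 10, 19 of the remaining 38 were higher and 1 lower, and the median was 0.66 on the log2 scale (camera adjusted p = 4.34e-36, and adjusted p = 0.00816 with an estimated correlation), a test chosen after seeing the data. The remaining genes still included the collagen genes Col12a1, Col5a2 and Col6a3, and no fibroblast profile was measured. This test therefore cannot separate a rise of matrix genes from fibroblast RNA.

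Genes for enzymes that cross-link, cleave or bind the matrix also rose. In the list of matrix remodelling enzymes and inhibitors, 28 of 56 tested members were higher and 5 lower, and adjusted over the list alone 33 were higher and 5 lower (camera adjusted p = 3.24e-18, and adjusted p = 0.0145 with an estimated correlation). The lysyl oxidase genes Lox, Loxl1 and Loxl2, whose products cross-link collagen, rose by 3.69 ± 0.25, 3.34 ± 0.29 and 3.28 ± 0.31 on the log2 scale (SE), from levels under 1 CPM in the PDPN-negative libraries. Mrc2, which encodes an endocytic collagen receptor, rose from 0.170 ± 0.0718 to 2.65 ± 0.731 CPM (SD, n = 5 each). Of the members that fell, Serpinb2, an inhibitor of plasminogen activators, went from 27.1 ± 14.0 to 3.07 ± 3.57 CPM, and Ctsk, which encodes the collagen-degrading protease cathepsin K, from 76.6 ± 31.7 to 13.4 ± 10.2 CPM (edgeR adjusted p = 0.0119 and 0.0114). Both collagen-handling groups were measured beside the rise in fibroblast markers given above.

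**Figure D2:**
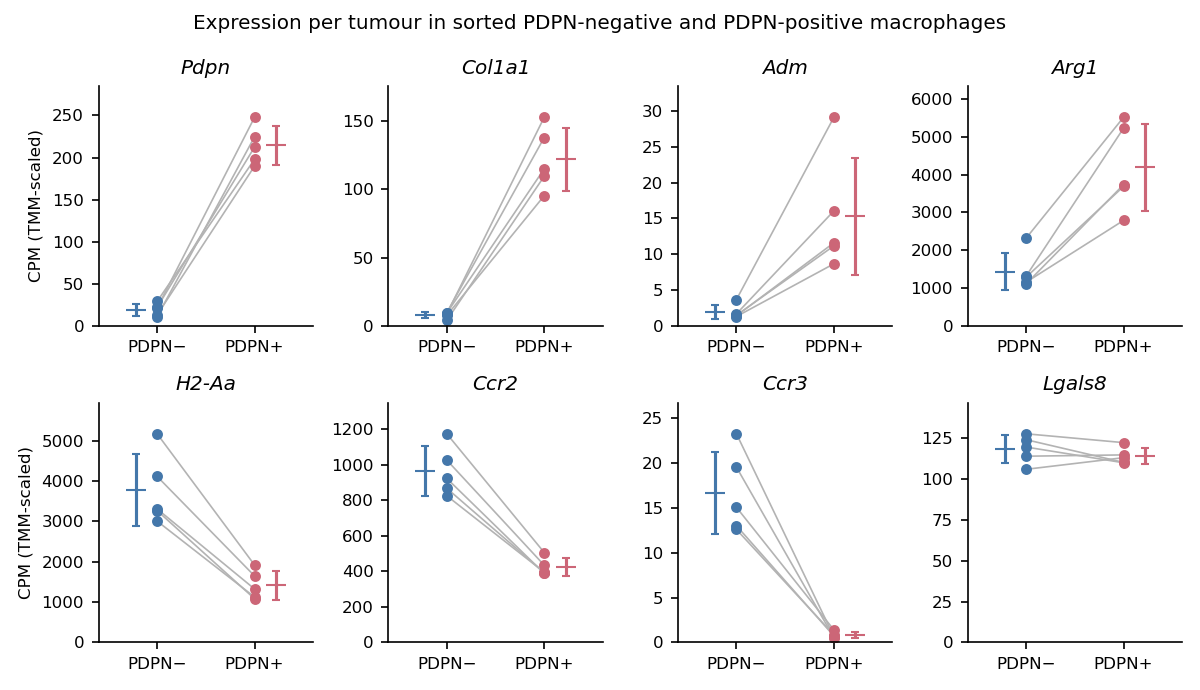
Expression in CPM (vertical axes, from 0) of 8 genes in the PDPN-negative (blue) and PDPN-positive (red) library of each of 5 tumours, with grey lines joining the 2 libraries of a tumour and the mean ± SD (n = 5) beside the points. Pdpn, Col1a1, Adm and Arg1 were higher and H2-Aa, Ccr2 and Ccr3 lower in the PDPN-positive library of all 5 tumours, whereas Lgals8 was higher in 2 of the 5.

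Genes tied to lymphatic vessel growth did not pass the test as a group without the block. Of 25 tested members of the lymphangiogenic list, 2 were higher and none lower, both over all genes and adjusted over the list alone (camera adjusted p = 0.179, and adjusted p = 0.493 with an estimated correlation). With the tumour as a block, 7 were higher and 1 lower and the list passed the threshold (camera adjusted p = 0.0374, and adjusted p = 0.24 with an estimated correlation). Fibroblast markers were higher in the same libraries (16 of 19, median 2.81 on the log2 scale). The members that rose were Adm, whose product acts on endothelial cells, at 15.3 ± 8.15 against 1.92 ± 0.994 CPM (SD, n = 5 each, edgeR adjusted p = 0.00114), and Svep1, which encodes a secreted matrix protein needed for lymphatic development, at 3.20 ± 1.32 against 0.213 ± 0.146 CPM (edgeR adjusted p = 2e-04). Flt4, which encodes the receptor VEGFR3, and the hyaluronan receptor gene Lyve1 did not pass the test (log2 fold changes of 0.26 ± 0.37 and 0.24 ± 0.45, SE). Without PDPN-positive tumour 5 the value for Flt4 was -0.05. Vegfc, the main ligand of VEGFR3, lay below the filter for the edgeR test. It had 14 counts in all PDPN-positive and 64 in all PDPN-negative libraries, or 0.2002 ± 0.151 against 0.928 ± 0.423 CPM (SD, n = 5 each), and was lower in 5 of 5 tumours (exact permutation test, two-sided p = 0.00794, the smallest this test can give, and 0.0397 after Benjamini-Hochberg adjustment over 10 genes below the filter). By pairs the exact two-sided p was 0.0625, the smallest that 5 pairs allow.

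Galectin and integrin genes, whose products link cells to matrix glycoproteins, were measured as separate lists. Lgals8, which encodes galectin 8, did not differ by more than the spread between libraries, at 113.9 ± 5.02 against 118.1 ± 8.55 CPM (SD, n = 5 each, log2 fold change -0.05 ± 0.06 SE, edgeR adjusted p = 0.624). Lgals3 rose from 502.8 ± 80.2 to 1018 ± 152 CPM (log2 fold change 1.02 ± 0.12 SE, edgeR adjusted p = 2e-04) and Lgals1 by 0.40 ± 0.10 (adjusted p = 0.0253, and 0.0663 at most when PDPN-negative tumour 2 or PDPN-positive tumour 4, 5 or 6 was left out), so that 2 of 6 galectin-list members were higher and none lower, also adjusted over the list alone. The galectin list did not pass the threshold (camera adjusted p = 0.0745, and adjusted p = 0.202 with an estimated correlation) but did with the tumour as a block (adjusted p = 0.026, but adjusted p = 0.288 with an estimated correlation in that fit), and without PDPN-positive tumour 1 (0.0374), PDPN-positive tumour 2 (0.0462) or PDPN-negative tumour 6 (0.0382). It also passed with block and GC correction (adjusted p = 0.0307) and with fry (0.00758). The fibroblast markers were higher in those libraries as well (median 2.81 on the log2 scale). Of 19 integrin genes, Itgb2 and Itgal, the chains of the leukocyte integrin LFA1, were higher, Itga2 and Itga2b were lower, and the list did not pass the test (2 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.414, and adjusted p = 0.684 with an estimated correlation). With the tumour as a block 4 integrin genes were higher and 5 lower. The call for Itgal was lost on leaving out any of 7 libraries. Itgb1, the common beta chain of matrix-binding integrins, differed by 0.05 ± 0.07 on the log2 scale (SE, adjusted p = 0.696).

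Hypoxia-inducible and glycolytic genes were higher in PDPN-positive libraries. Of 41 tested members 31 were higher and 1 lower, and adjusted over the list alone 34 were higher and 1 lower, with a median of 0.56 on the log2 scale (camera adjusted p = 8.89e-27, and adjusted p = 0.044 with an estimated correlation, or adjusted p = 0.079 with an estimated correlation and the tumour as a block). The fibroblast markers were higher in the same libraries (median 2.81 on the log2 scale), and eosinophil, neutrophil and monocyte markers were lower (medians -4.33, -1.44 and -1.19). Egln3, an oxygen-sensing prolyl hydroxylase gene that HIF induces, rose from 23.9 ± 4.601 to 75.3 ± 13.9 CPM (SD, n = 5 each, log2 fold change 1.65 ± 0.15 SE, edgeR adjusted p = 4.2e-05). The glycolytic gene Aldoa rose from 694.4 ± 43.6 to 1145 ± 102 CPM, and Ak4, a mitochondrial adenylate kinase gene, by 1.38 ± 0.15 on the log2 scale. The member that fell was the glucose transporter gene Slc2a3, from 25.7 ± 3.93 to 5.71 ± 1.598 CPM (edgeR adjusted p = 1.5e-05). Gapdh was listed at only 25.6 ± 6.37 and 28.4 ± 9.21 CPM. How reads shared with pseudogene copies were counted is not given in the sources used here, so the level of Gapdh is uncertain. Nuclear-encoded genes of oxidative phosphorylation did not pass the test as a list (1 of 41 higher, 0 adjusted over the list alone, camera adjusted p = 0.282, and adjusted p = 0.828 with an estimated correlation), and 6 were higher with the tumour as a block. That member was Uqcrb, whose call was lost on leaving out any of 9 libraries, with library size alone (adjusted p = 0.0528), with no filter on low counts (0.125) and with the DESeq2 test and block (0.191). The list passed without PDPN-negative tumour 6 (adjusted p = 0.0232). None of 7 mitochondrially encoded genes passed the edgeR test, mt-Nd6 and mt-Nd4 being nearest (list camera adjusted p = 0.936, and adjusted p = 0.982 with an estimated correlation).

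Cell cycle genes were higher in PDPN-positive libraries. In the proliferation list 28 of 40 members were higher and none lower, and adjusted over the list alone 36 were higher (median 0.52 on the log2 scale, camera adjusted p = 1.43e-17, but adjusted p = 0.246 with an estimated correlation). In the same libraries the fibroblast markers were higher (median 2.81 on the log2 scale) and eosinophil, neutrophil and monocyte markers lower (medians -4.33, -1.44 and -1.19). Plk1, a mitotic kinase gene, went from 22.8 ± 3.70 to 39.8 ± 6.05 CPM (SD, n = 5 each, edgeR adjusted p = 0.00132). Stmn1, Rrm2 and Cenpf were 1.796-fold, 1.56-fold and 1.596-fold higher.

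Antigen presentation genes were lower in PDPN-positive libraries. Of 12 tested genes of MHC class II presentation, 8 were lower and none higher, also adjusted over the list alone (median -0.92 on the log2 scale, camera adjusted p = 1.2e-09, but adjusted p = 0.146 with an estimated correlation, or 0.0496 with the tumour also as a block). Markers of monocytes, B and plasma cells, neutrophils and eosinophils were lower in the same libraries (medians -1.19, -1.21, -1.44 and -4.33 on the log2 scale), and fibroblast markers were higher (median 2.81). H2-Aa fell from 3774 ± 885 to 1420 ± 357 CPM (SD, n = 5 each, edgeR adjusted p = 0.000834), H2-Eb1 from 2925 ± 776 to 1066 ± 280, and the invariant chain gene Cd74 from 8920 ± 1852 to 4581 ± 972 CPM. H2-Ab1 fell by 1.25 ± 0.19 on the log2 scale. Of 33 type I interferon response genes 3 were lower (Isg20, Irf9 and Oas1a) and none higher, and adjusted over the list alone 12 were lower (camera adjusted p = 3.81e-06, but adjusted p = 0.493 with an estimated correlation and 0.12 with fry). The blocked fit had 26 of the 33 lower. The calls for Irf9 and Oas1a were lost on leaving out any of 6 and 8 libraries, respectively. Conventional dendritic cell markers were lower in the same libraries: 3 of 12 passed the test (Batf3, Cd24a and Dpp4), also adjusted over the list alone (camera adjusted p = 0.0104, 0.0532 without PDPN-negative tumour 2, 0.0962 with fry, and adjusted p = 0.493 with an estimated correlation). 6 of the 12 were lower with the tumour as a block. The call for Dpp4 was lost on leaving out any of 6 libraries.

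Neither textbook macrophage activation programme passed the test as a list moving in 1 direction. Both passed fry for changes in either direction (adjusted p = 8.54e-06 for alternative and 0.00296 for inflammatory activation). Alternative activation genes had 4 members higher and 4 lower of 30, also adjusted over the list alone (camera adjusted p = 0.949, and adjusted p = 0.983 with an estimated correlation). The median was 0.02 and the mean -0.09 on the log2 scale. Arg1, which encodes arginase 1, rose from 1438 ± 500 to 4191 ± 1146 CPM (SD, n = 5 each, edgeR adjusted p = 0.00263), the scavenger receptor gene Msr1 from 1102 ± 153 to 1684 ± 109 CPM and Cd200r1 by 0.56 ± 0.12 on the log2 scale, whereas the transcription factor gene Klf4 fell from 553.3 ± 75.3 to 332.4 ± 44.5 CPM. Inflammatory activation genes had 2 higher and 2 lower of 31, and 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.282, and adjusted p = 0.684 with an estimated correlation). With the tumour as a block 6 were higher and 11 lower. Nos2, which encodes the inducible nitric oxide synthase, was higher at 183.9 ± 87.7 against 50.1 ± 32.01 CPM and Ccl4 at 178.8 ± 39.4 against 134.9 ± 7.73 CPM. Both calls were lost on leaving out any of 5 and 9 libraries, respectively (highest edgeR adjusted p = 0.0774 and 0.119). They were also lost with no filter on low counts (0.0686 and 0.0894), and that of Ccl4 with DESeq2 size factors (0.0514) or limma-voom (0.0557). Socs3 and Nfkbiz fell by 0.44 ± 0.09 and 0.72 ± 0.14 on the log2 scale (SE).

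Of 25 chemokine genes, 7 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.0371, but adjusted p = 0.298 with an estimated correlation). The list's call was lost without PDPN-negative tumour 1 (adjusted p = 0.0978), without PDPN-positive tumour 5 (0.0867) and with a stricter filter on low counts (0.169), and 3 members were lower with the tumour as a block. Ppbp rose 5.58-fold and Cxcl3 3.71-fold, and both attract cells bearing CXCR2. Cxcl12, a product of stromal cells, rose from 0.369 ± 0.199 to 1.72 ± 0.796 CPM, and the monocyte attractant gene Ccl2 from 215.0 ± 29.5 to 361.3 ± 76.9 CPM (SD, n = 5 each). Lipid handling and phagolysosome genes had 10 higher and 1 lower of 36, and 12 higher and 2 lower adjusted over the list alone (camera adjusted p = 6.82e-05, but adjusted p = 0.146 with an estimated correlation). 19 were higher and 4 lower with the tumour as a block. The lysosomal protease gene Ctsd rose from 1734 ± 131 to 3048 ± 247 CPM (edgeR adjusted p = 3.95e-05), the lysosomal glycoprotein gene Gpnmb from 2.20 ± 0.824 to 11.8 ± 3.93 CPM and the tetraspanin gene Cd9 by 0.99 ± 0.15 on the log2 scale. Genes of glutathione metabolism and NRF2 targets had 9 of 21 higher and none lower, and 10 higher adjusted over the list alone (camera adjusted p = 6.12e-06, but adjusted p = 0.124 with an estimated correlation, or 0.0351 with the tumour also as a block). In the blocked fit 13 of them were higher and 1 lower. In the libraries where these chemokine, lipid and NRF2 genes were measured, fibroblast markers were higher (median 2.81 on the log2 scale) and eosinophil, neutrophil and monocyte markers lower (medians -4.33, -1.44 and -1.19). The iron exporter gene Slc40a1 rose 5.34-fold, the peroxidase gene Prdx1 1.36-fold, the ferritin heavy chain gene Fth1 1.35-fold and Gclm, needed for glutathione synthesis, 1.46-fold.

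A list of genes linked to tissue dissociation holds immediate early genes, which are induced within minutes of stimulation, and heat shock genes. In that list 14 of 26 members were lower and 1 higher, and adjusted over the list alone 15 were lower and 4 higher (camera adjusted p = 1.15e-09, and adjusted p = 0.0119 with an estimated correlation, or adjusted p = 0.101 with an estimated correlation and the tumour as a block). Eosinophil, neutrophil and monocyte markers were lower in the same libraries (medians -4.33, -1.44 and -1.19 on the log2 scale) and fibroblast markers higher (median 2.81). Btg2 fell from 931.2 ± 98.8 to 464.6 ± 50.5 CPM (SD, n = 5 each), Dusp2 from 80.1 ± 9.41 to 35.6 ± 5.65 CPM, Fosb from 1666 ± 135 to 1015 ± 112 CPM and Nr4a1 by 0.66 ± 0.08 on the log2 scale. The members that were higher adjusted over the list alone were heat shock genes, Hsph1, Hspa1b, Hspa1a and Hsp90aa1 (log2 fold changes of 0.63, 1.05, 0.75 and 0.23), and of these only Hsph1 passed over all genes. Genes of the TGF-beta response had 3 higher and 5 lower of 26, and 4 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.539, and adjusted p = 0.776 with an estimated correlation). The median was -0.06 and the mean 0.02 on the log2 scale, and 9 were higher and 7 lower with the tumour as a block. Ctgf rose from 0.6997 ± 0.224 to 2.46 ± 0.844 CPM, while Junb, Id3 and Tgif1 fell by 0.51 ± 0.07, 1.65 ± 0.25 and 0.45 ± 0.09. Complement and phagocytic receptor genes had 3 higher and 3 lower of 29, and 4 and 4 adjusted over the list alone, with a median of 0.01 and a mean of -0.01 on the log2 scale (camera adjusted p = 0.947, and adjusted p = 0.982 with an estimated correlation). With the tumour as a block 6 were higher and 6 lower. Besides Msr1, Stab1 and Mfge8 were higher and Scarb1 was lower, and these 3 calls were lost on leaving out any of 6, 8 and 3 libraries.

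**Figure D3:**
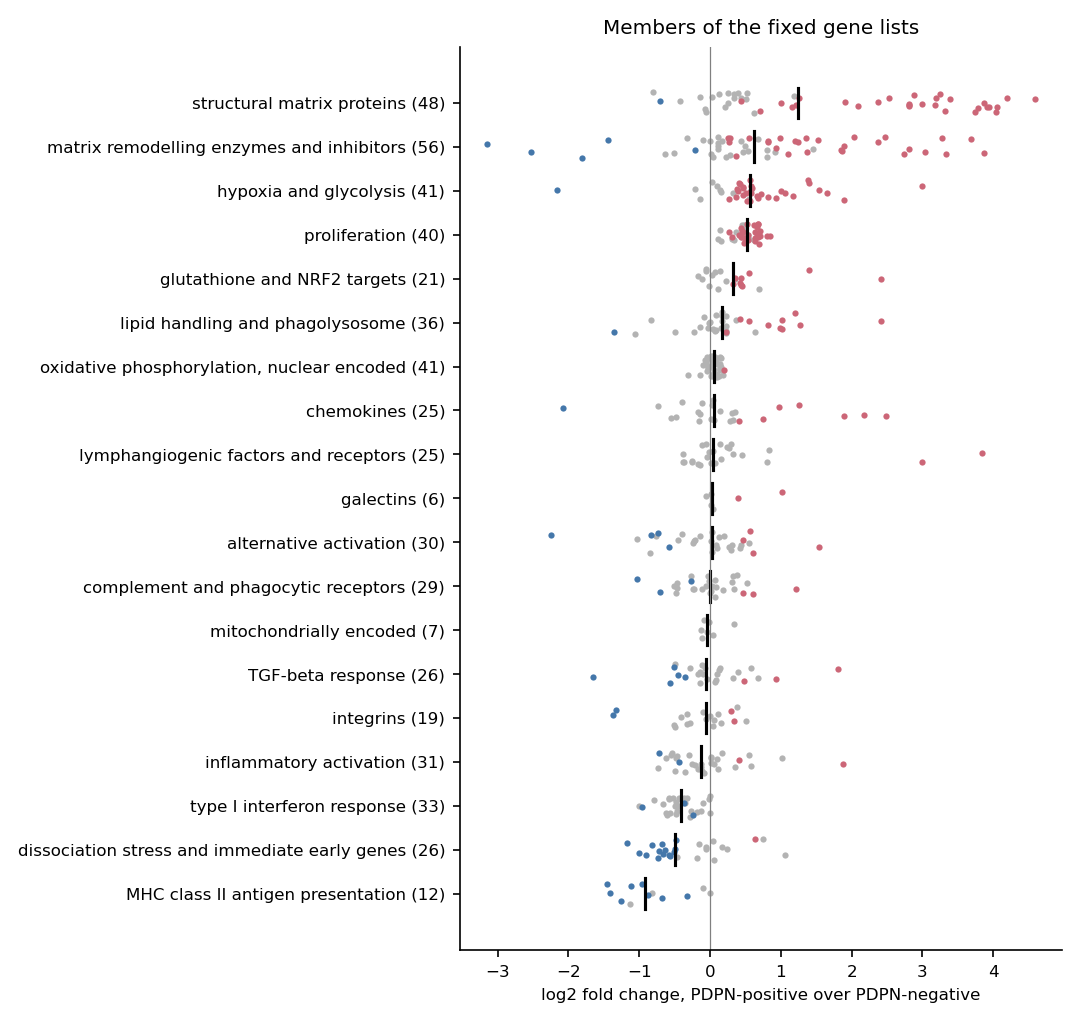
Log2 fold changes (horizontal axis, PDPN-positive over PDPN-negative, n = 5 each) of the tested members of 19 gene lists fixed before the data were examined, with the number of tested members in brackets. Red and blue points passed the edgeR test as higher or lower, grey points did not, and black bars are medians, which run from -0.92 for MHC class II genes to 1.24 for structural matrix proteins.

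Markers of other cell types that the sort could have admitted moved in both directions. Fibroblast markers were higher in PDPN-positive libraries, with 16 of 19 past the threshold and none lower, also adjusted over the list alone (camera adjusted p = 7.43e-46, and adjusted p = 0.00255 with an estimated correlation). They included Col3a1, at 140.6 ± 30.7 against 8.47 ± 2.76 CPM, and Col6a2 (SD, n = 5 each). Of 5 tested pericyte and smooth muscle genes, Tagln and Acta2 were higher (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.243, and adjusted p = 0.493 with an estimated correlation). All 3 tested eosinophil markers were lower, also adjusted over the list alone (median -4.33 on the log2 scale, camera adjusted p = 3.92e-20, and adjusted p = 0.00255 with an estimated correlation). Ccr3, which encodes the eotaxin receptor, measured 0.828 ± 0.337 against 16.7 ± 4.59 CPM, Siglecf 2.55 ± 0.956 against 16.4 ± 6.23 CPM and Il5ra, the interleukin 5 receptor gene, 0.0572 ± 0.0604 against 3.55 ± 0.966 CPM. Prg2, the gene of the main eosinophil granule protein, had 116 counts in the PDPN-negative and 0 in the PDPN-positive libraries, at least 38.3-fold lower when 3 counts over the group are taken as the floor, which covers counting error only. Neutrophil markers had 8 of 10 lower and 1 higher, also adjusted over the list alone (median -1.44 on the log2 scale, camera adjusted p = 1.12e-10, and adjusted p = 0.00255 with an estimated correlation). Retnlg measured 1.35 ± 0.426 against 47.3 ± 23.7 CPM, S100a8 and S100a9 were 2.65-fold and 3.04-fold lower, and Mmp8, a neutrophil collagenase gene, was 2.57-fold higher. Mast cell and basophil markers had 2 of 3 lower, Gata2 and Hdc, and 3 adjusted over the list alone (camera adjusted p = 7.05e-06, and adjusted p = 0.0409 with an estimated correlation, or adjusted p = 0.0647 with an estimated correlation and the tumour as a block).

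Monocyte markers were lower, with 6 of 11 past the threshold and none higher, and 8 lower adjusted over the list alone (median -1.19 on the log2 scale, camera adjusted p = 2.95e-07, but adjusted p = 0.124 with an estimated correlation, or 0.0156 with the tumour also as a block). In the blocked fit 9 of them were lower and 1 higher. Ccr2, the chemokine receptor of inflammatory monocytes, fell from 964.1 ± 140.1 to 423.7 ± 49.8 CPM (SD, n = 5 each, edgeR adjusted p = 2.34e-05). The list members Cd177, Hp and Ms4a4c were lower as well, in libraries where 8 of 10 neutrophil markers were also lower. Whether these members reflect monocytes alone was not tested. The call for Ly6c2, at 2.97 ± 1.55 against 15.9 ± 9.59 CPM, was lost on leaving out any of 5 libraries. Of 15 macrophage markers Itgam was higher and Aif1, Ptprc and Csf1r were lower, and 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.393, and adjusted p = 0.684 with an estimated correlation). 3 were higher and 7 lower with the tumour as a block. The calls for Itgam, Ptprc and Csf1r were lost on leaving out any of 8, 5 and 8 libraries. Cd68 missed the threshold (log2 fold change 0.22 ± 0.09 SE, adjusted p = 0.109) and passed it with the tumour as a block (adjusted p = 0.00582).

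Epithelial and 4T1 markers did not pass the test as a list, with 1 of 16 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.133, 0.0339 without PDPN-positive tumour 6, and adjusted p = 0.544 with an estimated correlation). With the tumour as a block 2 were higher and 4 lower. Cdh3 was 4.12-fold higher and Lcn2 2.46-fold lower, and Epcam, at 2.14 ± 0.672 against 3.32 ± 0.583 CPM (SD, n = 5 each), missed the threshold (adjusted p = 0.0889) but passed with the tumour as a block (adjusted p = 0.0356). Lymphatic endothelial markers had 0 of 6 past the threshold, also adjusted over the list alone (camera adjusted p = 0.591, and adjusted p = 0.828 with an estimated correlation). Their nearest members were Tie1 and Pecam1, of which Pecam1 passed with the tumour as a block (log2 fold change 0.48 ± 0.37 SE, adjusted p = 0.452, and 0.000147 with the block). Blood endothelial markers had 1 of 6 higher, Vwf, also adjusted over the list alone (camera adjusted p = 0.697, and adjusted p = 0.828 with an estimated correlation). Among T and NK cell markers 2 of 5 were higher (Il7r and Thy1) and 1 lower (Cd4), and 2 and 2 adjusted over the list alone. That list's median was -0.68 while its mean was 0.25 on the log2 scale (camera adjusted p = 0.0582 towards higher, and adjusted p = 0.298 with an estimated correlation). The list passed without PDPN-negative tumour 2 (adjusted p = 0.000519) and without PDPN-positive tumour 1 (0.0374), 2 (0.0438), 4 (0.0346) or 5 (0.00581). B cell and plasma cell markers had 2 of 4 lower, Cd79b and Ighm, also adjusted over the list alone (camera adjusted p = 0.024, but adjusted p = 0.298 with an estimated correlation), and the call for Ighm was lost on leaving out any of 8 libraries. Plasmacytoid dendritic cell markers had 0 of 4 past the threshold and 1 higher adjusted over the list alone (camera adjusted p = 0.756, and adjusted p = 0.828 with an estimated correlation). Among them, Runx2 and Tcf4 passed with the tumour as a block (adjusted p = 0.00253 and 0.0487). The adipocyte list had 1 tested gene, Fabp4 (edgeR adjusted p = 0.215), and the red blood cell list had 0, so neither list was tested.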

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

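The tests of the explanations below were chosen after the values had been seen, except the count of other splits of the libraries. Among 100 of the 126 ways to split the 10 libraries into 5 and 5, the real split included, 1 gave as many as 1849 genes, the real one. The highest of the others gave 20. These other splits mixed the sorted fractions, which adds their difference to the spread within groups, and many did not keep the tumour pairs. The count of splits therefore cannot exclude chance. Of the 16 splits that part all 5 pairs, the real one gave 1849 genes (3830 with the tumour as a block) and each of the other 15 gave 0 in both fits, but 16 splits are too few for a share under 0.05.

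Fibrillar collagens and other fibroblast markers rose in PDPN-positive libraries (16 of 19). PDPN is carried by activated fibroblasts, which the gate on CD11B and F4/80 should have removed unless attached to a macrophage. Markers of fibroblasts that are not matrix proteins rose too: the median log2 fold change of 7 was 0.879 and 4 of them passed the test (Pdgfra, Pdgfrb, Prrx1 and Thy1), so that some fibroblast RNA in the PDPN-positive libraries remains a candidate explanation, although Fap (-0.12), Twist1 (-0.08) and Pi16 (0.43) did not pass; the most abundant fibroblast markers were Col3a1 and Col1a1, at 140.6 and 121.9 CPM. For the rise of Fn1, Spp1, Mmp12, Arg1 and Ctsd, the summed CPM gain of 19 fibroblast markers was at most 0.0467 of the summed gain of these 5 genes in any tumour, but a part played by fibroblast RNA stays open for them, since no fibroblast profile was measured. Whether macrophages of this sort express collagen themselves also stays open and was not tested.

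Eosinophil and neutrophil markers fell in PDPN-positive libraries. Eosinophils carry CD11B and, in mice, F4/80, so the gate may admit them, and RNA of eosinophils in the PDPN-negative libraries is a candidate explanation. The 4 eosinophil markers too low for the edgeR test (Epx, Prg2, Ear6 and Ear1) had 135 counts in PDPN-negative and 0 in PDPN-positive libraries, a ratio of 0 with an exact upper 95% bound of 0.028, which covers counting error only. Of the 135 counts, 116 were of Prg2, so the ratio rests mainly on that gene. The PDPN-negative libraries held from 7 to 55 of them each. A lower share of macrophages in the PDPN-negative fraction could raise the markers of other cell types there. The median of the fibroblast markers went the other way, at 2.81 on the log2 scale against -4.33 for eosinophils. As activated fibroblasts carry PDPN, the sort itself could have set that direction. The comparison therefore cannot decide on the share of macrophages. Eosinophil RNA was not tested as the source of the neutrophil genes, and a difference between the 2 kinds of macrophage stays open and untested.

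Hypoxia and glycolysis genes rose in PDPN-positive libraries. A trend with GC content does not account for it, as 97.6% of the list's median in the blocked fit was kept with GC correction (0.56 before and 0.55 after, 34 genes higher in both). The gain of the fibroblast markers was at most 0.116 of the gain of the 31 raised genes in any tumour, or 0.19 without Arg1, and fibroblast RNA stays open here too, since its share of these genes was not measured. Position of the cells in the tumour was not measured, and a biological difference between the sorted groups remains a hypothesis.

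Some libraries lay far from the other 4 of their group by Dixon's test at 5%. It singled out 25 of 316 groups of values (7.91%). The cut-off gives about 5% for independent, normally distributed values. Most values here were untransformed CPM of related genes, so 5% need not be the rate by chance. In PDPN-negative tumour 6, values were highest for Loxl1 (0.658 CPM, others up to 0.328), Lgals3 (640.3, others up to 495.6), Arg1 (2320, others up to 1317) and Mfge8 (55.9, others up to 29.5). PDPN-negative tumour 2 was highest for Slc2a3 (32.4 CPM), Dpp4 (20.4), Thy1 (4.06) and the mean log2 CPM of the MHC class II list (9.10, others up to 8.52). PDPN-negative tumour 5 was highest for Adm (3.68 CPM, others up to 1.68) and lowest for Uqcrb (21.5, others from 23.1). PDPN-negative tumour 4 was highest for Ctsd (1965 CPM, others up to 1705). PDPN-positive tumour 6 accounted for 8 of the 25. It was highest for G0s2 (2.87 CPM), Cxcl3 (57.2), Ctgf (3.96), Csf1r (2801), Tagln (4.81), Acta2 (6.44) and Adgre1 (650.1), and lowest for Lcn2 (0.698). PDPN-positive tumour 5 was highest for Cxcl12 (3.12 CPM), Egln3 (99.7) and Ak4 (38.5). PDPN-positive tumour 4 was lowest for Cd177 (0.391 CPM) and Gata2 (0.0652), and PDPN-positive tumour 2 was highest for Serpinb2 (9.39, others up to 2.06).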

How the results depend on the processing

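The GC correction and the matrix list without fibroblast markers were chosen after seeing the data; the other alternatives were planned. Counts moved by over 1.5 times with the tumour as a replicate block (1880 higher, 1950 lower), with the DESeq2 Wald test and block (1445 lower), with the tumour as a random effect in limma-voom (1925 higher, 1885 lower; correlation 0.406), against a minimum change of 1.5-fold (135 higher, 84 lower), and with the block and GC correction (1855 higher, 2088 lower). The common biological coefficient of variation was 7.55% with the block and 13.3% without it, and why the counts rose was not tested. Without the block, left-out libraries or tumours gave 437 to 1049 genes higher and 482 to 1026 lower, and fewer libraries were then tested. With the block kept, no count moved by over 1.5 times when a tumour was left out. The share of higher calls stayed within 10 points under the other scalings, and the median of all genes moved by less than 0.1.

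The lymphangiogenic list passed with the block (adjusted p = 0.0374) and with block and GC correction (0.0344) and ranged from 0.0767 to 0.291 with a library left out. Apart from it, the galectin list, Runx2, Tcf4, Pecam1, Cd68 and Epcam, the block in the edgeR fit changed no call of a named gene, or of a list at the preset correlation. With an estimated correlation, the block ended the calls of hypoxia, dissociation stress and immediate early genes and mast cells and gave calls to MHC class II, NRF2 targets and monocytes, with the values given beside each list. Lists that were not called also changed direction: integrins with the stricter filter (0.986), alternative activation with upper quartile scaling or library size alone (both 0.97), complement with the block (0.837), block and GC correction (0.82) or fry (0.958), mitochondrial genes with block and GC correction (0.795) and blood endothelium with the stricter filter (0.746). With 1 library left out, the adjusted p ran from 0.5 to 0.917 for alternative activation, from 0.645 to 0.931 for complement, from 0.374 to 0.989 for mitochondrial genes, from 0.5 to 0.998 for plasmacytoid dendritic cells and from 0.445 to 0.99 for blood endothelium. Flt4 ranged from -0.051 to 0.402 on the log2 scale. The cause of these changes was not tested. Of 17 called lists, 9 lost their call in at least 1 of the 19 alternatives run for lists with 1 choice changed or with block and GC correction, 0 by reversal. The other 8 did not, but hypoxia, dissociation stress and immediate early genes and mast cells lost it with block and estimated correlation together, as above. The stricter filter left too few members to test eosinophil, mast cell, B cell, T and NK cell and pericyte lists. Of 106 called genes among those named, 90 kept their call and direction in each alternative that tested them and 16 lost the call somewhere, while 5 of the other 14 gained it. Named genes were not followed against the minimum change of 1.5-fold or with both libraries of a tumour left out. Calls held only without PDPN-positive tumour 2 for Ccl4 and Uqcrb, without PDPN-positive 2 or PDPN-negative 6 for Mfge8 and Ighm, without PDPN-negative 1 or PDPN-positive 2 for Oas1a, without PDPN-negative 5 or PDPN-positive 5 for Itgam, and without PDPN-negative 1 or PDPN-positive 6 for Csf1r. They held without PDPN-negative 1 or 2 or PDPN-positive 6 for Itgal, without PDPN-negative 1 or 6 or PDPN-positive 2 or 5 for Irf9, without PDPN-negative 4 or 5 or PDPN-positive 2 or 5 for Stab1, and without PDPN-negative 2, 4 or 6 or PDPN-positive 2 for Dpp4, and were lost without each other library. They were lost without PDPN-positive 1, 4 or 6 or PDPN-negative 2 or 5 for Ly6c2 and Ptprc, without PDPN-negative 1, 2 or 4 or PDPN-positive 5 or 6 for Nos2, and without PDPN-negative 2 or PDPN-positive 4 or 5 for Scarb1. The T and NK cell list also passed with library size alone (0.0433), with block and GC correction (0.0307) and with fry (0.0261). The galectin list also passed with block and GC correction (0.0307) and with fry (0.00758), and fry ended the calls of the interferon (0.12) and conventional dendritic cell (0.0962) lists. Runx2 passed without PDPN-positive 1 or 4, with upper quartile scaling (0.0414), library size alone (0.0381), no filter on low counts (0.0369) and the DESeq2 Wald test (0.0334), and Tcf4 without PDPN-negative 6 (0.0127). With no filter on low counts, the calls of Ly6c2 (adjusted p = 0.0635), Mfge8 (0.0857), Itgam (0.0587), Csf1r (0.0699), Dpp4 (0.106) and Ighm (0.0982) were lost. That of Itgal was lost with DESeq2 size factors (0.0504) and the stricter filter (0.051), and that of Ighm with library size alone (0.0539). As 1 count was worth at least 0.0649 CPM, genes under 1 CPM rest on few counts, and Vegfc was compared outside the edgeR test.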

Other observations

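The genes in this part were chosen after their values were seen. Fibroblast markers were higher in the same PDPN-positive libraries (16 of 19, median 2.81 on the log2 scale), and eosinophil, neutrophil and monocyte markers lower (medians -4.33, -1.44 and -1.19). Which cells the changes in this part came from was not tested. Among cell surface genes outside the lists, PDPN-positive libraries had more Tnfrsf9, a costimulatory receptor gene (83.6 ± 17.2 against 18.9 ± 7.30 CPM, SD, n = 5 each), and Ackr3, which encodes a scavenging receptor of CXCL12 (39.9 ± 9.47 against 7.65 ± 2.26 CPM), and both were higher in 5 of 5 tumours (edgeR adjusted p = 0.000363 and 0.000138). Il7r, which stood among the T cell markers, rose from 16.3 ± 1.71 to 69.0 ± 15.3 CPM. The hypoxia-responsive factor gene Epas1 rose from 17.9 ± 6.99 to 59.3 ± 21.3 CPM and Notch4 from 5.43 ± 2.58 to 16.0 ± 4.82 CPM. Both enzymes that compete for arginine, Arg1 and Nos2, were higher together with the arginine transporter gene Slc7a2 (219.8 ± 89.9 against 56.1 ± 18.3 CPM, edgeR adjusted p = 0.00524), whereas Odc1, which acts downstream of arginase, did not pass the test (adjusted p = 0.666).

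In the other direction, the neighbouring genes Tmem176a and Tmem176b on chromosome 6 fell from 177.6 ± 51.1 to 35.4 ± 8.53 CPM and from 299.2 ± 75.6 to 66.2 ± 17.2 CPM (edgeR adjusted p = 0.000235 and 0.000264), each in 5 of 5 tumours. The adhesion receptor gene Adgre5 fell from 326.7 ± 116.4 to 120.6 ± 14.9 CPM and the nuclear receptor gene Pparg from 6.32 ± 2.72 to 2.41 ± 0.993 CPM. Of the 13595 genes, 4756 (35.0%) had the same sign in all 5 tumours, where chance gives 6.25%. Lymphatic endothelial genes below the filter were rare in both groups: Prox1 had 15 counts in PDPN-positive and 8 in PDPN-negative libraries, and Ccl21a had 0 in both.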
